A study of Mus musculus with 6 samples.

How the data were processed

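RNA from C8-D1A cells, a cloned mouse astrocyte line, was measured on 6 one-colour Agilent arrays, 3 from untreated cells (control) and 3 from cells given pulsed radiofrequency (PRF), an electrical stimulation delivered in short high-frequency bursts. Per the labels' protocols, 15 × 10,000 cells were seeded per well in plates of 12 wells, kept for 6 days in medium with 10% serum and moved to serum-free medium for 24 h before use. The labels give 3 independent experiments, a lowest RNA integrity number of 9.5, and Cy3-labelled RNA made with a low-input amplification kit. The settings of the stimulation, its duration and the time between stimulation and RNA extraction are not given in the sources used here.

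The deposited intensity values of each array are scanner output made with Agilent Feature Extraction 10.7.3.1, per the file headers: a background-corrected processed signal, a median signal and a local background per spot, with flags for saturated spots, outlier spots and spots well above background. Normalization between arrays had not been applied to them. The authors' deposited series table holds intensity on a linear scale as well. Its values equalled the processed signal within a relative tolerance of 0.0001 for 99.5% of the probes of each array, and its column medians were 41.4, 36.5 and 36.3 for the control arrays and 50.0, 41.1 and 39.3 for the PRF arrays, so it had been neither centred nor log transformed. How the authors normalized and tested these values is not given in the sources used here.

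Signals were put on the log2 scale, control spots were left out and spots of the same probe were averaged (300 probes were spotted 10 times), which left 56605 probes. The 75th percentile of each array was then subtracted. Levels below are log2 signals relative to that percentile. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which 34838 probes were. A probe near background in control cells therefore entered the test only if it was bright in PRF cells. Models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A plain threshold, an unadjusted p below 0.05 with a change of at least 1.5-fold, was used as well.

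The files give accessions and no gene names, so probes were named through the transcripts of the RefSeq table of assembly GRCm38.p6. A symbol was found for 32994 probes, covering 22911 genes, and 23611 probes stayed without a name. The array design refers to an older mouse build than that table, so no coordinates are given. The probe with the highest mean over the 6 arrays stood for its gene, which gave 15069 tested genes. Among the genes named below as changed, the 1 further tested probe of Bhlhe41, Il6ra, Rps2 and Zfp493 and 1 of the 2 further probes of Mtf1 did not pass. Where a probe was not well above background on any array of a group, only a bound is given: "at least N-fold" is the mean of the brighter group over the dim group's mean of, per array, the higher of the lowest normalized signal among probes well above background and the probe's own signal. The symbols Hspa1a and Hspa1b, and likewise Rpph1 and Rprl1 to Rprl3, stand for near-identical copies whose probes may bind each other's RNA, so their separate values are uncertain.

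Before the data were examined, 38 gene lists, the tests and the rule for named genes were fixed. Lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 38 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. The rule named the 12 largest rises and the 12 largest falls among genes past the adjusted threshold whose groups did not overlap, up to 4 members of each called list, up to 2 members of other lists with an unadjusted p below 0.05, and a fixed set of glial, cytokine, growth factor and stress genes. Values of some genes that the rule takes are not reported here. The 12 largest rises and falls among genes well above background on all 6 arrays were added after the values were seen. Hsph1, Klf2, Gdf15, Id4, Sox2, Bik, Snap25, Mt1, Mt2, the Fgf genes other than Fgf2, and the small RNAs other than Rprl2 and Rprl3 were also chosen after their values were seen.

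On simulated arrays with the spread of the measured ones, 34838 probes in all, 100 probes were changed 1.5-fold and 100 were changed 2-fold. For PRF against control limma recovered 29% and 58% of them, with 4 false calls and 0 calls of the wrong sign. Noise was drawn independently for each probe, and far fewer probes were changed than the 10823 called on the measured arrays. These rates therefore need not hold for the measured arrays. In simulated data over 15069 genes, camera called the 1 shifted list and 0 of 20 unchanged lists. These genes varied independently and the lists were drawn at random. The simulation therefore cannot show how often camera calls unchanged lists whose genes vary together. The arrays lay on 1 slide scanned once, so slide and scan could not differ between groups. Array row held both groups and was tried as a block. Array column followed the replicate number. The other alternatives were normexp background correction (offset 50), quantile normalization, scaling by the median of the tested probes, no filter on dim probes, a filter asking for all 6 arrays, a replicate block, an eBayes fit with trend and robust settings, the deposited table on its own scale, 1 probe per gene, outlier spots left out, each array left out in turn, a 2-fold threshold and Welch's test per probe at the plain threshold. The array files used here hold no column of spot means, so normexp was run on spot medians. Scaling to the E1A spike-in probes, whose amounts the labels do not state, and fits within each array row were added after the data were seen. Each row holds 1 array of a group, so such a fit assumes that this lone array varies like those of the other group.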

Results

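The comparison asked how gene expression in cultured astrocytes differs after PRF, a stimulation used against neuropathic pain, from that in untreated cells. Of 56605 probes, between 33670 and 34642 were well above background on the 3 control arrays (59.5% to 61.2%) and between 35146 and 36191 on the 3 PRF arrays (62.1% to 63.9%). The 75th percentile of the signal was 675, 635 and 598 on the control arrays and 634, 544 and 553 on the PRF arrays, and 1 spot was saturated on 1 array. The number of arrays, 3 per group, limits the precision of the values below. Their p-values measure the spread between 3 independent experiments.

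After PRF, 18 of 30 tested heat shock genes, 32 of 44 immediate early genes and the RNase P RNAs were higher, and 11 of 16 replication-dependent histone genes and 11 of 45 cell cycle genes were lower. Hspa1a, which encodes the inducible HSP70 chaperone, was 32.4-fold higher (log2 level 3.08 ± 0.03 in control and 8.10 ± 0.11 in PRF cells, SD, n = 3, adjusted p = 1.09e-05). Egr1, a growth factor-induced transcription factor, was 7.25-fold higher (1.26 ± 0.19 against 4.11 ± 0.22, SD, n = 3, adjusted p = 9.96e-05). Rpph1, the RNA component of ribonuclease P, was 62.3-fold higher (0.29 ± 0.22 against 6.26 ± 0.24, SD, n = 3, adjusted p = 2.9e-05). H1f5, a linker histone made during DNA replication, fell by 1.17 on the log2 scale (SE 0.09, adjusted p = 4.27e-04). Gfap, the classical marker of reactive astrocytes, had levels of -2.76 ± 0.03 and -2.68 ± 0.15 (SD, n = 3), a difference smaller than the spread of the PRF arrays (adjusted p = 0.548).

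**Figure D1:**
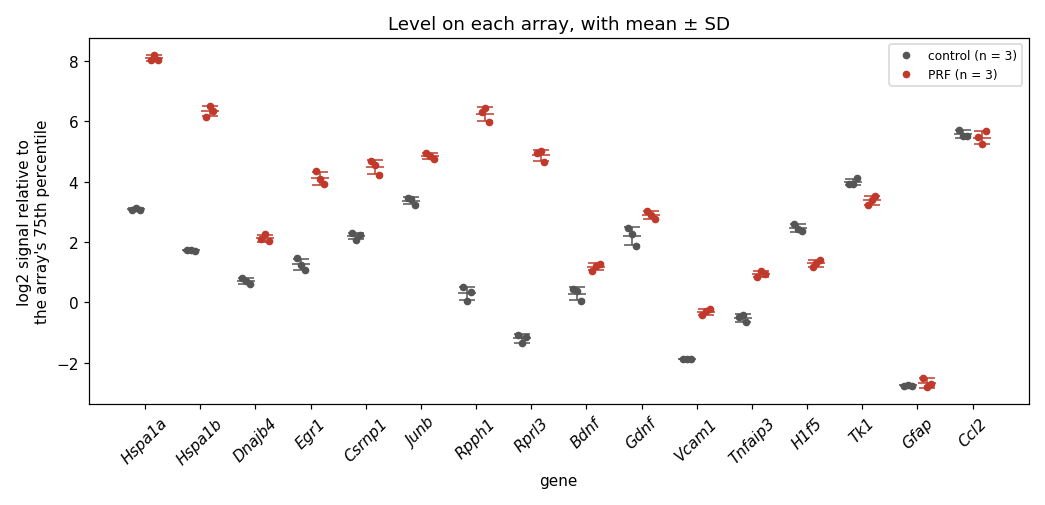
Level of 16 genes on each array (y axis, log2 signal relative to the array's 75th percentile), with points for the 3 control arrays in grey and the 3 PRF arrays in red and bars for mean ± SD. The groups of Hspa1a, with means of 3.08 and 8.10, lie far apart, whereas those of Gfap and Ccl2 overlap.

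Across the array, 10823 of 34838 probes passed the adjusted threshold, 6430 higher and 4393 lower in PRF cells. At gene level 4489 of 15069 genes passed, 2466 upward and 2023 downward. Large changes were mostly rises, with 1214 genes at least 2-fold higher and 78 at least 2-fold lower. The filter adds to this balance, since genes dim in the controls were tested only if bright after PRF. Of the 2466 rises, 473 were of such genes. With the filter asking for all 6 arrays, 4954 probes were called upward and 4479 downward. At the plain threshold 2920 passed upward and 1367 downward with that filter. In 51.1% of the genes the 3 PRF arrays lay wholly on one side of the 3 control arrays, where chance gives 10%. The first principal component of the tested probes held 87.0% of the variance and separated the groups. Correlations between arrays ranged from 0.994 to 0.997 within groups and from 0.959 to 0.977 between them. At the plain threshold 6224 probes passed, 4664 upward. An unadjusted p below 0.05 was reached by 14964 probes, where chance would give 1742. The balance of all called probes depended on the scaling: 59.4% were rises with the 75th percentile, 49.5% with the median of the tested probes, 41.6% with quantile normalization, 38.3% on the deposited scale and 28.8% with spike-in scaling. Probes called with at least a 2-fold change were mostly rises under each of these scalings, from 2907 against 257 with the 75th percentile to 2364 against 748 with quantile normalization. With normexp they were fewer, 1015 against 31. With array row as a block 8514 probes were called, against 3072 within row 1 and 164 within row 2, which hold 3 arrays each. At the plain threshold, where no adjustment enters, the counts were 6255, 6429 and 5550, and normexp background correction gave 3043.

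Among the 12 largest rises by the fitted change, 10 genes were not well above background on any control array. Only bounds can be given for them, and their rank is uncertain. Rpph1 (62.3-fold), Rprl1 (44.9-fold), Wfdc3 (36.3-fold) and Hspa1a (32.4-fold) lay outside the 12, although their rises exceeded several of these bounds. Ccdc81 rose at least 47.2-fold, Erich4 at least 45.3-fold, Gm6588 at least 31.6-fold and Tac2, which encodes the neurokinin B precursor, at least 25.7-fold. Rhox6, Wfdc9, Apol10a, Kcnk6, Rab42 and Obox6 rose at least 23.4, 23.2, 22.7, 21.8, 19.6 and 15.9-fold. The fit's adjusted p for these 10 genes ran from 2.75e-05 for Tac2 to 3.83e-04 for Apol10a. The remaining 2 were Rprl3 and Rprl2, RNase P RNA-like genes, with rises of 6.07 (SE 0.12) and 6.06 (SE 0.14) on the log2 scale. In all, 483 tested genes were not well above background on any control array, and 473 of them passed the test upward. Only 16 tested genes were not well above background on any PRF array, and 12 of them passed downward. The filter let such genes in only if they were bright in the other group, so these counts follow largely from it. Of all probes not well above background on any control array, 5.38% were well above it on all PRF arrays. The reverse held for 0.42% of the probes not well above background on any PRF array.

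**Figure D2:**
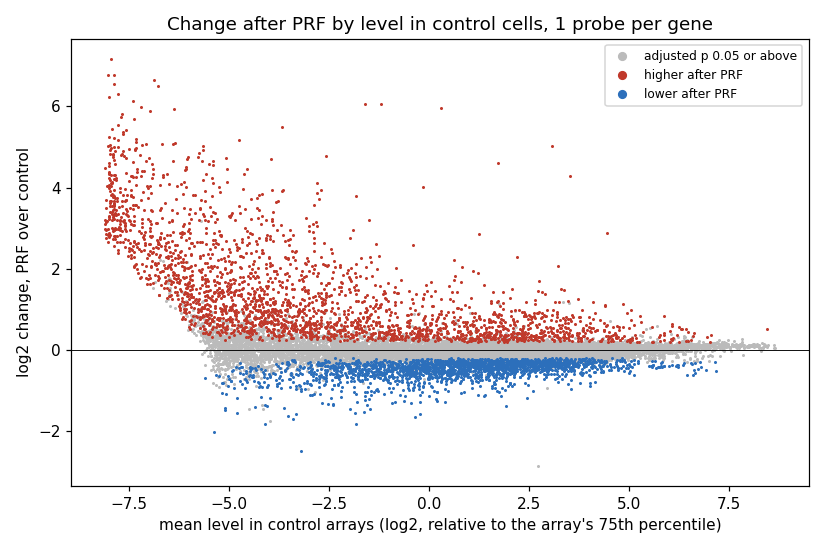
Log2 change of PRF over control (y axis) against the mean level in control arrays (x axis, log2 relative to the array's 75th percentile) for 15069 genes, with 2466 genes higher after PRF in red, 2023 lower in blue and the rest in grey. Rises of more than 16-fold lie mostly at low control levels, where a gene could be tested only if it was bright after PRF.

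Among genes well above background on all 6 arrays, the largest rises after the RNase P RNAs (Rprl3, Rprl2, Rpph1 and Rprl1) were those of Wfdc3 (36.3-fold), Hspa1a (32.4-fold) and Fpr2, a formyl peptide receptor of innate immune cells (27.3-fold). Gm34526, 1700016G22Rik, Ifna12, Hspa1b and Il17re followed, between 26.4-fold and 23.6-fold higher. Mean control levels of Wfdc3, Gm34526, Ifna12 and Il17re were low, at -4.74, -5.07, -5.40 and -5.41, against 3.08 for Hspa1a. Their folds therefore rest on dim control signals and are less certain. Falls were smaller. Tlr7, an endosomal receptor for single-stranded RNA, had the largest (5.56-fold lower, adjusted p = 0.00493), with 2 of 3 PRF arrays well above background. Gm16008 was well above background on all control arrays and on no PRF array (at least 1.25-fold lower, adjusted p = 0.011). Wfdc13 was 3.53-fold lower, Mc3r 3.51-fold, the zinc finger genes Zfp354b and Zfp493 3.26 and 2.98-fold, Erich5 3.12-fold, Olfr339 2.97-fold, Klrb1a 2.95-fold, C2cd4d 2.94-fold and 9130019O22Rik 2.86-fold, and Zkscan4, also a zinc finger gene, fell by 1.63 on the log2 scale. Of these, Olfr339 and Zkscan4 were well above background on 2 PRF arrays, and Mc3r and Klrb1a on 1. The other tested probe of Zfp493 did not pass. Mc3r and Olfr339 missed the threshold without control replicate 1 or 3 or PRF replicate 2 (adjusted p from 0.0513 to 0.0613), and Klrb1a without any array other than PRF replicate 3 (adjusted p from 0.0701 to 0.097). With normexp Gm16008 and Klrb1a missed it (adjusted p = 0.398 and 0.383).

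Of 38 gene lists, 9 were called by camera, 7 upward and 2 downward. None of the 9 was called with an estimated correlation, where adjusted p-values were 0.553 or 0.559 and 1 list, the neurotrophic factors, had an unadjusted p below 0.05 (p = 0.0267), and fry called 29 lists. Other splits of the same 6 arrays into 3 and 3 gave between 0 and 9 called lists, although none of them called a probe, so the number of called lists does not set the real groups apart. All 9 calls held with array row as a block. Within rows 1 and 2 the immediate early list had medians of 0.81 and 0.74, heat shock of 0.41 and 0.39, neurotrophic factors of 0.30 and 0.20, glucocorticoid targets of 0.84 and 0.31, replication histones of -0.44 and -0.32 and the cell cycle list of -0.13 and -0.13.

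Heat shock genes rose together. Of 30 tested members 18 rose and 0 fell (19 and 0 adjusted over the list alone), and the median change was 0.39 on the log2 scale (camera adjusted p = 5.63e-07, and adjusted p = 0.553 with an estimated correlation). The median was 0.25 on the deposited scale and 0.19 with spike-in scaling. Hspa1b was 24.6-fold higher (SE 0.10 on the log2 scale, adjusted p = 1.54e-05). Hspb1, the small chaperone HSP27, was well above background on 1 of 3 control arrays and on all PRF arrays, with a log2 rise of 5.93 (SE 0.31). Hsph1, a partner of HSP70, rose by 2.06 (SE 0.17), and Dnajb4, an HSP40 co-chaperone, by 1.42 (SE 0.09), each with 2 further probes that also rose.

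The immediate early list had the smallest camera p (adjusted p = 5.75e-08, and adjusted p = 0.553 with an estimated correlation). Of its 44 tested genes 32 rose and 3 fell (34 and 4 adjusted over the list alone), and 16 of the rises were at least 2-fold. Csrnp1 rose by 2.29 (SE 0.13) on the log2 scale, Junb, an AP-1 subunit, by 1.48 (SE 0.09) and Phlda1 by 1.13 (SE 0.08). Klf2, a transcription factor known from endothelial cells, fell by 1.02 (SE 0.07). Fos, the best known member of the group, had levels of 3.49 ± 0.06 and 3.61 ± 0.07 (SD, n = 3) and did not pass (adjusted p = 0.235). Its change was of the opposite sign on the deposited scale and with spike-in scaling.

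Genes for growth and survival factors of neurons also rose as a list (camera adjusted p = 0.0123, and adjusted p = 0.553 with an estimated correlation). Of 30 tested members 12 rose and 0 fell (13 and 1 adjusted over the list alone). The median change of 0.29 on the log2 scale was 0.17 with quantile normalization, 0.15 on the deposited scale and 0.092 with spike-in scaling. Bdnf, the brain-derived neurotrophic factor, was 1.85-fold higher (SE 0.12 on the log2 scale, adjusted p = 0.00345), Gdnf, the glial cell line-derived factor, 1.63-fold (adjusted p = 0.0181, and 0.0594, 0.0579 and 0.0783 without PRF replicate 1, without PRF replicate 2 and on the deposited scale), Fgf2 1.92-fold, Cntf 1.67-fold and Lif 3.18-fold. Nrg1, a ligand of ErbB receptors, was not well above background in control cells and rose at least 4.27-fold (adjusted p = 6.57e-05).

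In the list of inflammatory cytokines and their regulators, 12 of 27 tested genes rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.0136, and adjusted p = 0.553 with an estimated correlation). The median of 0.29 on the log2 scale was 0.19 with quantile normalization, 0.15 on the deposited scale, 0.094 with spike-in scaling and 0.19 without control replicate 3. The call was missed within array row 1 (adjusted p = 0.0553, with a range from 0.00181 to 0.0553 over 18 alternatives). The members that rose included Vcam1, an adhesion molecule, by 1.56 (SE 0.07) on the log2 scale, Tnfaip3 and Nfkbiz, regulators of NF-kB signalling, by 1.45 (SE 0.09) and 1.28 (SE 0.07), complement C3 by 1.96 (SE 0.16) and the chemokine Cxcl10 by 1.18 (SE 0.20). Il6, Ccl2 and Tnf did not pass. Il6 levels were -4.69 ± 0.18 and -4.21 ± 0.35 (adjusted p = 0.101, but 0.00879 with normexp and 0.0412 without PRF replicate 2), Ccl2 levels 5.59 ± 0.12 and 5.46 ± 0.22 (adjusted p = 0.502) and Tnf levels -3.60 ± 0.21 and -3.52 ± 0.12 (SD, n = 3, adjusted p = 0.631). No probe of Il1b was well above background on any array.

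Of 16 tested genes known to respond to glucocorticoids 7 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00184, and adjusted p = 0.553 with an estimated correlation). The median was 0.51 on the log2 scale and 0.32 with spike-in scaling. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 17.5-fold, Dusp1 1.86-fold and the kinase Sgk1 1.76-fold, and Cdkn1c, a cyclin-dependent kinase inhibitor, at least 2.54-fold. Several of these genes also respond to other stimuli.

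Replication-dependent histone genes fell. Of 16 tested members 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.44 on the log2 scale (camera adjusted p = 1.34e-05, and adjusted p = 0.553 with an estimated correlation). H1f3 was 2.41-fold, H1f5 2.25-fold, H2ac11 1.49-fold and H2ac20 1.40-fold lower. RNA of these histone genes lacks a poly(A) tail, and whether labelling contributed to the fall was not tested. In the cell cycle list 11 of 45 genes fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.00187, and adjusted p = 0.553 with an estimated correlation), which was -0.27 on the deposited scale and -0.33 with spike-in scaling. Tk1, a thymidine kinase of S phase, was 1.53-fold lower, the mitotic kinase Plk1 1.40-fold and the cyclin Ccne1 1.32-fold.

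The other 2 called lists moved little. Ribosomal protein genes had a median of 0.13 on the log2 scale, and 2 of 44 rose, Rpl37 and Rps2 (1 adjusted over the list alone, camera adjusted p = 4.71e-04, and adjusted p = 0.559 with an estimated correlation). Cholesterol synthesis genes had a median of 0.14, and 5 of 25 rose, among them Msmo1 by 0.33 (0 adjusted over the list alone, camera adjusted p = 0.0108, and adjusted p = 0.553 with an estimated correlation). Both calls ended on the deposited scale (adjusted p = 0.143 for both) and with spike-in scaling (adjusted p = 0.422 and 0.213), where both medians fell below 0. The ribosomal call ended with quantile normalization too (adjusted p = 0.189), and the cholesterol call within array row 2 (adjusted p = 0.441). Over 18 alternatives the adjusted p ran from 3.94e-06 to 0.422 for the ribosomal list and from 0.00186 to 0.441 for the cholesterol list. Rps2 missed the threshold without any 1 array (adjusted p from 0.0912 to 0.125), and Msmo1 without control replicate 2 or 3 or PRF replicate 1 or 2 (adjusted p from 0.0559 to 0.0783).

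**Figure D3:**
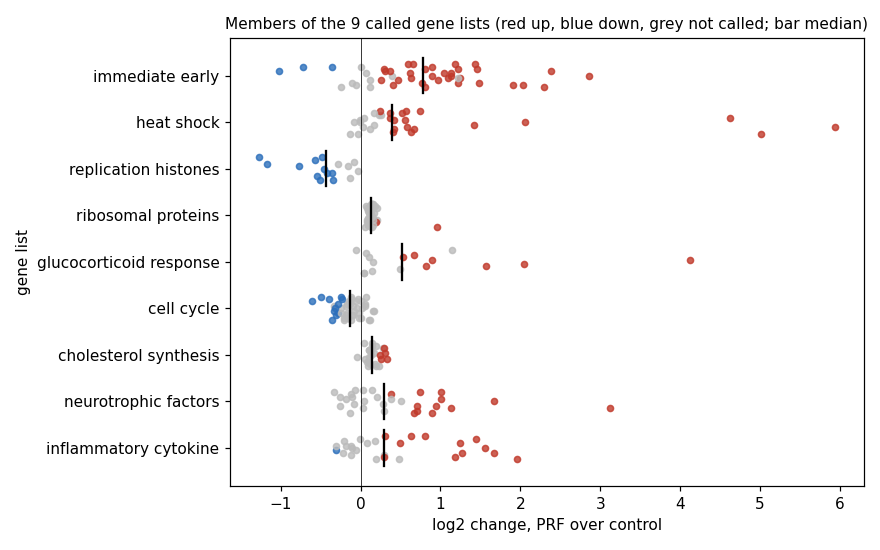
Log2 change of PRF over control (x axis) for each tested member of the 9 called gene lists (y axis), with rises past the adjusted threshold in red, falls in blue, other members in grey and a black bar at each list's median. The immediate early list has the highest median, 0.79, and replication histones the lowest, -0.44.

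Some of the 29 lists that were not called held single genes with large changes. In the list of pain-related signalling 11 of 36 tested genes rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.188). Edn1, the precursor of endothelin 1, was 15.4-fold higher (adjusted p = 1.25e-04) and the adenosine receptor gene Adora2a 2.63-fold (adjusted p = 9.60e-05). Among 28 tested astrocyte identity genes 4 rose and 2 fell (camera adjusted p = 0.269). Apoe was 2.13-fold and Clu 1.46-fold higher, Id4 1.86-fold and Sox2 1.31-fold lower. Slc1a2, a glutamate transporter, had levels of -2.93 ± 0.15 and -3.03 ± 0.07 (SD, n = 3, adjusted p = 0.468, but 0.0344 with quantile normalization and 0.0347 with spike-in scaling, both downward), and no probe of Gja1 or Slc1a3 was well above background on any array. Markers of reactive astrocytes rose in 3 of 11 pan-reactive genes, 4 of 10 A1 genes and 1 of 7 A2 genes, and 1 A2 gene, Sphk1, fell (camera adjusted p = 0.248, 0.0737 and 0.418). The A1 list was called upward on the deposited scale (adjusted p = 0.0435), with spike-in scaling (adjusted p = 0.0406) and without control replicate 1 (adjusted p = 0.0209), with a range from 0.0209 to 0.158 over 17 alternatives, a replicate block apart. Adjusted over the list alone, 5 A1 genes rose and 1 fell, and the counts of the other lists were the same. Sphk1 missed the threshold without any 1 control array or PRF replicate 3 (adjusted p from 0.0617 to 0.0926).

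Among stress and survival lists, 9 of 29 p53 targets rose and 4 fell (camera adjusted p = 0.188), with Fas 2.59-fold and Gadd45g 1.62-fold higher. Gdf15, a stress-induced cytokine, was 11.4-fold higher (SE 0.47 on the log2 scale), with 2 of 3 control arrays well above background. In the apoptosis list 2 of 26 genes rose and 8 fell (camera adjusted p = 0.314). The rises were those of Mcl1 (2.17-fold) and Cflar (1.84-fold), both inhibitors of apoptosis. Bik, a pro-apoptotic gene chosen after its value was seen, was among the falls (1.80-fold). The other falls are not named, so these genes do not show a direction of the list. Of 35 genes of the unfolded protein and integrated stress responses 7 rose and 0 fell (camera adjusted p = 0.188), with Ppp1r15a 2.84-fold and Nupr1 1.61-fold higher. Of 28 oxidative stress genes 2 rose and 5 fell (camera adjusted p = 0.378), with Osgin1 1.52-fold higher and Cbr3 1.38-fold lower. Among 7 genes of the metal response list Mtf1 (1.78-fold) and Slc30a1 (1.61-fold) rose (camera adjusted p = 0.289). Oxidative phosphorylation had 0 calls in 33 genes by limma at the adjusted threshold, where 1 gene had an unadjusted p below 0.05 and fry did not call the list (adjusted p = 0.088). Adjusted over the list alone, 10 p53 targets rose and 4 fell, 5 stress response genes rose, 2 oxidative stress genes rose and 3 fell, and the counts of the others were the same. Without 1 array, PRF replicate 2 excepted, Bik missed the threshold (adjusted p from 0.0645 to 0.119), as did Slc30a1 with PRF replicate 3 excepted (adjusted p from 0.0641 to 0.103). Slc30a1 also missed it without the filter (adjusted p = 0.0750), with array row as a block (adjusted p = 0.0638), on the deposited scale (adjusted p = 0.104) and with spike-in scaling (adjusted p = 0.0746).

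In the other signalling lists some genes passed. Among all 15069 tested genes 29.8% passed, 2466 upward and 2023 downward, and most of these lists had a similar or smaller share. Interferon response genes rose in 3 of 30 and fell in 1 (Psmb8 3.27-fold, with 1 control array well above background, and Dhx58 2.74-fold higher), and STAT3 signalling genes rose in 5 of 16 and fell in 1 (Il6ra 1.77-fold higher). Clock genes rose in 7 of 21 and fell in 1 (Nfil3 4.62-fold and Bhlhe41 1.57-fold higher). TGF-beta and matrix genes rose in 11 of 37 (Col1a2 6.58-fold with 1 control array well above background, Skil 1.63-fold), and targets of SRF and YAP rose in 7 of 29 (Ccn1 3.76-fold, Amotl2 3.30-fold). Hypoxia and glycolysis genes rose in 8 of 34 and fell in 1 (Ankrd37 at least 3.61-fold, Eno2 1.37-fold higher). Calcium signalling genes rose in 5 of 30 and fell in 4 (Rcan1 2.32-fold higher). Autophagy genes rose in 6 of 34 and fell in 1 (Gabarapl1 1.33-fold higher, Neu1 1.76-fold lower). Lipid efflux genes rose in 5 of 22 and fell in 4, fatty acid synthesis genes fell in 2 of 18 (Agpat2 1.38-fold, Srebf1 1.21-fold), Wnt, Notch and Hedgehog genes rose in 3 of 22 (Dll1 1.86-fold, Jag1 1.46-fold) and synaptogenic matrix genes rose in 2 of 18 and fell in 1 (Cspg5 3.53-fold higher, Efnb1 1.27-fold lower). Camera adjusted p-values of these 12 lists were 0.0612 or higher, but 4 of the lists were called upward under some of the same 17 alternatives. The interferon list was called under 9 of them, with adjusted p = 2.13e-04 without control replicate 1, 0.00779 with spike-in scaling, 0.0107 within array row 2, 0.0158 with the filter asking for all 6 arrays, 0.0201 on the deposited scale, 0.0217 with quantile normalization, 0.0253 with median scaling, 0.0312 without PRF replicate 3 and 0.0329 with normexp. The clock list was called under 5, with adjusted p = 0.0158 with the filter asking for all 6 arrays, 0.0212 within array row 1, 0.0452 without control replicate 2, 0.0465 with spike-in scaling and 0.0468 with median scaling. The TGF-beta and matrix list was called without PRF replicate 1 (adjusted p = 0.0307), with the filter asking for all 6 arrays (adjusted p = 0.0419) and without control replicate 2 (adjusted p = 0.0452), and the hypoxia list with that filter (adjusted p = 0.0419). The highest adjusted p over these alternatives was 0.261, 0.343, 0.237 and 0.422 for the interferon, clock, TGF-beta and hypoxia lists. Adjusted over the list alone, 2 interferon genes rose and 1 fell, 1 autophagy gene rose and 1 fell, 1 fatty acid gene fell, and the counts of the others were the same. Without 1 array, Psmb8 (control replicate 2 or 3 or PRF replicate 2), Eno2 (control or PRF replicate 1 or 2) and Srebf1 (any but PRF replicate 3) missed the threshold, with adjusted p from 0.0531 to 0.102. Eno2, Gabarapl1 and Jag1 missed it on the deposited scale (adjusted p = 0.0878, 0.116 and 0.0698), Eno2 and Gabarapl1 with spike-in scaling (adjusted p = 0.0976 and 0.0985) and Eno2 with quantile normalization (adjusted p = 0.753).

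Markers of other cell types moved unevenly. Neuronal markers rose in 4 of 13 and fell in 1, with Nefh at least 6.53-fold, Slc32a1 at least 6.23-fold and Snap25 1.96-fold higher. Oligodendrocyte markers rose in 3 of 14 and fell in 3, with Cldn11 at least 8.63-fold and Mobp at least 3.29-fold higher. Microglial markers rose in 3 of 10 (Laptm5 7.30-fold with 1 control array well above background, Itgam 1.81-fold), endothelial markers in 1 of 7 (Kdr at least 2.40-fold), ependymal markers in 1 of 6 (Folr1 2.39-fold, with 2 control arrays well above background), and fibroblast and pericyte markers in 4 of 11 with 2 falls (Anpep at least 7.11-fold higher). None of these 6 lists was called (camera adjusted p from 0.181 to 0.865). The markers that fell are not named. Nefh, Slc32a1, Cldn11, Mobp, Kdr and Anpep were dim on all control arrays and were tested only because they were bright after PRF. Markers dim in both groups were not tested, which left 13 of 22 neuronal, 10 of 21 microglial and 7 of 15 endothelial markers. Adjusted over the list alone, 4 neuronal markers rose and 3 fell, 4 oligodendrocyte markers rose and 4 fell, 4 microglial markers rose and 1 fell, and 5 fibroblast and pericyte markers rose and 2 fell.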

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

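Spike-in scaling and fits within array rows were chosen after the data were seen. The heat shock, immediate early, neurotrophic, glucocorticoid, histone and cell cycle calls held under 18 alternative settings of the values, and all of them were lost with an estimated correlation (adjusted p = 0.553). The trend and robust fit and 1 probe per gene leave the list test as it is and are not among the 18. The count of called probes stayed within 1.5 times 10823 except with 1 probe per gene (4842, fewer features tested) and within array row 1 (3072) or row 2 (164), which hold 3 arrays each, and with Welch's test (2165). With array row as a block it was 8514. Leaving out 1 array gave 7223 to 10662 called probes, 5553 to 6944 past the plain threshold, 9 to 11 called lists and 85.5% to 89.3% of the variance on the separating component. The plain count of 6224 became 3043 with normexp, 2337 with 1 probe per gene and 3250 at 2-fold. Welch's test gave 5398 at the plain threshold. Called lists numbered 0 with an estimated correlation and 29 with fry. The separating component held 82.5% with normexp, 85.6% with quantile normalization and 65.5% without the filter. Where no construction explains a change, the cause was not tested. Spike-in scaling moved the median change of the tested probes by -0.20 and the deposited scale by -0.14.

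The arrays do not show that replicate numbers pair them: residual correlations of same-numbered arrays were 0.14, -0.08 and 0.04, and 1 of 3 control arrays correlated best with its own number. With the replicate block 9392 probes were called, 6217 passed the plain threshold and 12 lists were called, among them interferon response (adjusted p = 0.00587), A1 markers (0.0271) and clock genes (0.0385).

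Small changes of genes that did not pass changed sign. Gfap was -0.11 with quantile normalization, -0.064 on the deposited scale, -0.12 with spike-in scaling and -0.036 within row 1, and ran from -0.0057 (without PRF replicate 1) to 0.14 when 1 array was left out. Tnf was -0.21 with quantile normalization, -0.055 on the deposited scale and -0.11 with spike-in scaling, and ran from -0.035 (without control replicate 2) to 0.15 when 1 array was left out. Fos was -0.022 on the deposited scale and -0.076 with spike-in scaling. Within row 2 Ccl2 was 0.072 and Slc1a2 0.038. With spike-in scaling Mt1 was -0.045, Mt2 -0.054 and Rps2, which had passed, -0.0023. Mt2 was -5.9e-05 on the deposited scale. Of 150 named genes, 117 lost their call within row 2 and 50 within row 1, and at most 16 did when 1 array was left out. Signal near background limits the values of dim genes to bounds.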

Other observations

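All tests in this part except that of neighbouring genes were chosen after the results were seen. Among 91 gene families formed from the letters that open a symbol, each with at least 15 tested genes, 5 passed camera's adjusted threshold, and none did with an estimated correlation (adjusted p = 0.889). A member dim in the controls was counted only if bright after PRF, which favours rises. The families were not run with the filter asking for all 6 arrays. Zinc finger genes named Zfp fell in 136 and rose in 28 of 342 cases (median -0.23 on the log2 scale, adjusted p = 2.65e-07). Their median stayed below 0 under each of the 6 scalings compared, from -0.20 with normexp to -0.43 with spike-in scaling. With spike-in scaling 227 fell and 16 rose. Fibroblast growth factor genes rose in 12 of 17 cases and fell in 1 (adjusted p = 0.0025). Fgf18 was 8.88-fold and Fgf7 2.32-fold higher, and Fgf22 at least 4.40-fold, while Fgf13 fell by 0.76 with 1 PRF array well above background and missed the threshold without any 1 array other than PRF replicate 2 (adjusted p from 0.060 to 0.106) and with normexp (adjusted p = 0.771). Protocadherin beta genes fell in 5 of 19 cases (adjusted p = 0.0231, and 0.123 with normexp and 0.103 with spike-in scaling). Vomeronasal receptor genes rose in 15 of 41 and fell in 2 (adjusted p = 0.0172). With quantile normalization 10 of them rose and 9 fell, and their median was below 0 (adjusted p = 0.506). Ribosomal Rpl genes rose in 2 of 50 (median 0.12, adjusted p = 0.0025). Their call ended with quantile normalization (adjusted p = 0.470), on the deposited scale (adjusted p = 0.238) and with spike-in scaling (adjusted p = 0.554), and their median was below 0 under the last 2.

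The share of large rises was counted by class of transcript. Among tested probes, 6.14% of those with a curated coding accession (NM) rose at least 2-fold past the adjusted threshold, against 18.1% of predicted non-coding accessions (XR), 13.7% of curated non-coding ones (NR) 15.1% of probes placed by chromosome range, 12.7% of cDNA clone accessions (AK) and 7.46% of Ensembl transcripts. The differences between classes were not tested, and such rises lay mostly at low control levels (1774 of 4355 probes in the lowest octile against 16 of 4355 in the highest), so class and level were not separated. The filter adds to the contrast between octiles, since probes dim in the controls were tested only if bright after PRF. Of 1133 such probes 1111 were called upward. The 3 PRF arrays differed in the size of the change: over the called probes, the slope of an array's change on the mean change ranged from 0.871 to 1.13.

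With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Every other split has arrays of both groups on each side. The difference between control and PRF then adds to the spread within its sides and lowers its probe counts. Such splits therefore do not show what arrays without a difference would give. The real split had 10823 called probes and the highest other 0, 6224 against 223 probes past the plain threshold, and 84.8% against 19.8% of the variance between its groups, so 1 split reached the real value in each case. It had 9 called lists and the highest other split also 9, so 2 splits reached that value.

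The first pattern is the rise of heat shock genes. Binding between the copies Hspa1a and Hspa1b cannot be the whole cause, since 57.1% of the other 28 list members also rose. Release of metal ions that induce metallothioneins stays open. The changes of Mt1 and Mt2 had 95% upper bounds no higher than 0.39 on the log2 scale, which argues against a 2-fold rise. Their control levels were high, 7.31 and 7.34, but no array was saturated for them and Hspa1a reached 8.10 in PRF cells. A smaller rise is not excluded. In the metal response list Mtf1 (1.78-fold) and Slc30a1 (1.61-fold) rose, and 1 of the 2 further Mtf1 probes did not pass. The call of Slc30a1 was missed without any 1 array other than PRF replicate 3 (adjusted p from 0.0641 to 0.103). Whether a rise of Mtf1 RNA follows from metal ions was not tested. Warming of the medium or a direct effect of the field may each account for the pattern and were not tested, because no temperature-matched group is among the samples.

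The second pattern is the rise of RNAs known as products of RNA polymerase III, a group put together by symbol after the values were seen and not tested as a list, so that all 9 of its tested members rose may follow from the choice. Rn7sk rose by 4.29, Rmrp by 4.02, Vaultrc5 by 3.57, Rn7s1 by 2.88 and Rn4.5s by 0.51 on the log2 scale, beside the RNase P RNAs. Signal at the background floor in control cells is argued against, as 100% of the members that rose were well above background on all 3 control arrays. As the whole cause, a general gain of RNA without a poly(A) tail is argued against by 20 genes outside this group. These snRNA, snoRNA, scaRNA and rRNA genes had a median change of 0.13, with a 95% upper bound of 0.44 (10000 resamples of the genes). That bound reflects the spread between genes and leaves out the spread between the 3 experiments. Of the 20 genes 8 rose and 1 fell, with 5 of 6 snRNA genes among the rises, so a smaller general gain stays open. Replication histone genes, whose RNA also lacks a poly(A) tail, fell in 11 of 16 cases and rose in 0 (median -0.44). A change in the synthesis, decay or tailing of the RNA polymerase III products after PRF stays open as a hypothesis and was not tested.

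The third pattern is the appearance of genes that were near background in control cells. Genomic DNA carried into the PRF samples would raise such probes broadly: 5.38% of the 21065 probes that were not well above background on any control array were so on all PRF arrays, but the lower quartile of the unscaled signal was 2.90, 2.78 and 2.83 on the control arrays and 4.18, 3.48 and 3.15 on the PRF arrays, so a small broad gain stays open. Read-through from active neighbouring genes was tested with a prediction written before the result. Of 459 induced genes 87.8% had an adjacent gene well above background on all control arrays, against 69.7% of 5523 genes that stayed silent (odds ratio 3.12, 95% interval 2.34 to 4.23, Fisher's exact test, two-sided p = 1.28e-18, olfactory, vomeronasal and trace amine receptor genes left out). Read-through would give this enrichment, but open chromatin near active genes may give it too, since strand was not used. A direct effect of PRF on these genes was not tested. Fisher's test counts genes as independent although adjacent genes share neighbours, so its interval and p may be too narrow. Induced and silent genes were not matched for gene density.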
